A study of Mus musculus and Homo sapiens with 61 samples.

How the data were processed

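The labels describe human spleen from patients with sepsis after injury or with injury alone, and spleen and blood of C57BL/6 mice after CLP, a sham operation, LPS, saline or no treatment. The abbreviation ABX is used as the labels give it. The design text of the series names 6 injured patients, of whom the sixth is not analysed here. Per the labels, total RNA was labelled with biotin and hybridised to Affymetrix arrays, of type Hu6800 for the human samples.

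The values were hybridisation intensity per probe set, as deposited by the authors in a human spleen table holding 5356 probe sets and another for both mouse tissues with 12488 probe sets. How the authors scaled or summarised these values is not given in the sources used here. Gene symbols came from annotation tables of the array types, with 4204 human and 10855 mouse probe sets naming 1 gene, 211 and 396 naming several and 898 and 1193 naming none. Of the mouse Entrez numbers 10839 were found in the GRCm38.p6 RefSeq table, in which 0 symbols differed, and no coordinates were used. Human spleen, mouse spleen and blood were fitted separately, apart from a fit of all mouse arrays for the difference of the CLP effects between tissues.

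From there, values under the 20th percentile of each species' table (859.7 human, 90.14 mouse) were raised to it and log2 was taken, so that fold changes of dim probe sets are understated. Between 17.56% and 24.21% of the values on an array stood at that floor. Quantile normalization was to be used if array medians spanned 0.3 log2 units or more, and they spanned 0.177, 0.0969 and 0.165 in human spleen, mouse spleen and blood, so none was applied. The 58 human and 66 mouse control probe sets and those under the 30th percentile of mean level were left out, which left 3702 human and 8695 mouse probe sets in each tissue.

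Differences were tested with limma's moderated linear model, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 33 blood arrays were fitted together, with the batch of the labels as a fixed block. The blood replicate number is that batch, and arrays of 1 batch deviated together with a mean correlation of 0.459 (−0.134 to 0.851). Batch 2 lacked a saline array and batch 3 a sham array, so contrasts with these controls had 4 batches holding both groups. Infected blood was the mean of 3 group means and not infected blood the mean of 4.

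The 27 gene lists were neutrophil granule and maturation, inflammatory cytokines and their antagonists, interferon response, innate sensing and NF-kappaB, MHC class II presentation, B cell, plasma cell, T cell, natural killer and cytotoxic, monocyte and macrophage, erythroid, platelet and megakaryocyte, cell cycle, apoptosis regulators, glucocorticoid response, heat shock and unfolded protein response, acute-phase with iron and metallothionein, glycolysis and hypoxia, mitochondrial respiratory chain, complement and coagulation, endothelial, stroma (fibroblast and smooth muscle), pancreatic acinar, adipocyte, liver, skeletal muscle, and other granulocytes (eosinophil, basophil and mast cell). Each gene was represented by its probe set of highest mean level, and lists with fewer than 5 measured genes were left out. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. Camera sets the genes of a list against all other genes tested, so a list can test as lower while its own median is near 0. In the monocyte and macrophage list, an alias of Slc40a1 matched Slc39a1, a zinc transporter, so that member is not the iron exporter meant.

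Genes were named by rule. In both spleens, in CLP and LPS blood and in infected blood these were the 8 largest rises and 8 largest falls among called probe sets of 1 gene, and elsewhere 5 each way, or all that passed if fewer did. Where none passed, the 5 of lowest p each way were named as not passing. Up to 4 members of lowest p could be named per list. The groups, gene lists, tests, naming rule and the alternatives planned were fixed before the data were examined.

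The classifier used the 50 probe sets of lowest limma p in the training batches, with batch-centred levels and equal class weights. The score of spleen genes in blood used batch-centred log2 levels. RNA quality was measured as the mean 3′ minus 5′ log2 difference of the Gapdh and actin control probe sets, and arrays were matched on that of Gapdh. The fits were tested on simulated data with 200 changed probe sets per comparison. Changes of 0.5, 1 and 2 log2 units were recovered in 79.1%, 100% and 100% of cases for mouse spleen, 67.2%, 97% and 98.5% for CLP blood, 55.2%, 95.5% and 100% for LPS blood and 26.9%, 79.1% and 100% for human spleen. False calls made up 5.58%, 5.91%, 4.02% and 2.14% of the calls. The simulated noise was drawn independently for each probe set and array. These rates may therefore not hold for the real calls, where probe sets can vary together. Alternatives tried were quantile normalization, other floors and filters, trend and robust variance, array weights, 1 probe set per gene, fits with other blocks or of the compared groups only, other classifier and score sizes, and leaving out each array. Software was R 4.3.3 with limma 3.58.1 and data.table (version 1.17.8), and Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9 for the plots.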

Results

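The data comprised 61 Affymetrix arrays of total RNA, of which 12 came from human spleen, 16 from mouse spleen and 33 from mouse blood. The human spleens were from 7 patients with sepsis after injury and 5 injured patients without sepsis. The mouse spleens comprised 8 arrays labelled cecal ligation and puncture (CLP), an operation that opens the bowel into the abdomen, and 8 labelled sham. The blood samples fell into 7 groups, with 5 arrays each of CLP, mild CLP, CLP+ABX, lipopolysaccharide (LPS, a bacterial cell wall component) and normal, and 4 each of sham and saline. The blood labels also gave every array 1 of 5 batches, and a class of infected (the CLP, mild CLP and CLP+ABX groups) or not infected (LPS, sham, saline and normal). Array medians ran from 2199 to 2485 intensity units in human spleen, from 212.6 to 227.4 in mouse spleen and from 221.5 to 248.4 in blood. The number of arrays limits the precision of what follows, and the labels do not state whether mouse replicates are separate animals, so p-values measure only the spread between these samples.

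The human comparison asked how the spleen differed between septic and injured patients. No single gene passed the adjusted threshold. HLA-DQA1 (probe set M26041_s_at), an MHC class II chain that presents antigen to T cells, had a log2 level of 12.42 ± 0.55 (SD, n = 7) in septic and 13.76 ± 0.32 (n = 5) in injured spleens, with 7 of 7 septic arrays below all injured arrays. The difference was −1.34 ± 0.25 (SE) with a limma adjusted p = 0.206, and the gene's other probe set differed by −1.98. TCL1A, a gene of immature and naive B cells, differed by −1.58 ± 0.32 with the same adjusted p of 0.206. The other 3 lowest genes were SP110 (−0.50), FYN (−0.69) and TRDV3 (−0.69), and the 5 highest were NME1 (0.64), LAMP2 (0.53), YWHAH (0.52), TUBB (0.59) and C1R (0.76), all at an adjusted p of 0.999.

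In gene lists tested with the preset correlation of limma's camera, 6 of the 22 lists measured in human spleen passed. The 17 neutrophil granule genes were higher as a list (median log2 difference 0.25, adjusted p = 0.000939), with 15 of 17 above 0, among them LCN2 at 0.74, MMP8 at 0.90 and MPO at 0.25. The 8 MHC class II genes were lower (median −0.26, adjusted p = 0.000684), including HLA-DPB1 at −0.74, HLA-DRB1 at −0.44 and HLA-DMB at −0.29. The 10 B cell markers were lower (median −0.27, adjusted p = 0.000684), with CR2 at −0.86, BLK at −0.42 and FCER2 at −0.39. The 10 T cell markers were lower (median −0.18, adjusted p = 0.0023), with IL7R at −0.59 and CCR7 at −0.47. These 4 lists had an adjusted p = 0.192 with an estimated correlation. The 6 natural killer and cytotoxic markers were lower (adjusted p = 0.0267), with GZMK at −0.40 and GZMA at −0.37, and the 13 respiratory chain genes were higher (adjusted p = 0.0118), with UQCRB at 0.49 and SDHC at 0.30. Their values were adjusted p = 0.43 and adjusted p = 0.479 with an estimated correlation. Over all genes tested, 0 members of any list passed, and adjusted over the list alone 2 B cell and 1 MHC class II genes were lower.

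In all, limma called 0 of 3702 human probe sets, with 136 at an unadjusted p under 0.05, where 185 were expected by chance. Leaving out injury replicate 5 or septic replicate 7 gave 1 call each. The natural killer list was lost without any 1 of injury replicates 1, 3 and 5 and septic replicates 2, 3, 4 and 6 (adjusted p of 0.0541 to 0.13), and the respiratory chain list without injury replicate 4 (0.202) or 5 (0.274) or septic replicate 2 (0.133) or 4 (0.0808). With the RNA quality covariate the natural killer and respiratory chain lists were lost, as was the natural killer list with the floor at the 40th percentile and the respiratory chain list with the 50th percentile filter. With that filter the B cell list had an adjusted p of 0.0545.

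The mouse spleen comparison asked how the organ differed after CLP and after the sham operation. Saa3, an acute-phase serum amyloid protein, rose 8.27-fold, from a log2 level of 9.13 ± 0.72 (SD, n = 8) in sham to 12.18 ± 0.27 (n = 8) in CLP, a difference of 3.05 ± 0.25 (SE, limma adjusted p = 8.41e-06). Lcn2, a neutrophil lipocalin that binds bacterial iron carriers, rose by 3.00 ± 0.29 (adjusted p = 2.56e-05), while its other probe set differed by 0.09. Marco, a scavenger receptor of macrophages, rose from 7.78 ± 0.63 to 10.04 ± 0.23 with the same adjusted p.

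Further rises were those of Socs3, an inhibitor of cytokine signalling (1.97 ± 0.26, adjusted p = 0.000401, and 0.75 at its other probe set, which also passed), S100a8, a calcium-binding protein of neutrophils (1.91 ± 0.29, 0.000743), and the transcription factor Cebpb (1.90 ± 0.24, 0.000232). Wfdc21 rose by 1.80 ± 0.23 (0.000232) and Lilr4b, an inhibitory leukocyte receptor, by 1.70 ± 0.24 (0.000497). For the first 7 of these genes, 8 of 8 CLP arrays lay above all sham arrays, and for Lilr4b 7 of 8. Falls were smaller. Tnnc1, a muscle troponin, fell by 1.12 ± 0.36 (0.0215), Klhl24 by 1.01 ± 0.33 (0.0231), Actb by 0.90 ± 0.21 (0.0052, with the other probe set at −0.09), and Rhd, a red cell membrane antigen, by 0.78 ± 0.30 (0.0421). Pa2g4 fell by 0.74, Alb, the albumin gene, by 0.70 ± 0.20 (0.013), Aanat by 0.69 ± 0.13 (0.00184) and 1110032A03Rik by 0.67 ± 0.23 (0.0277).

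**Figure D1:**
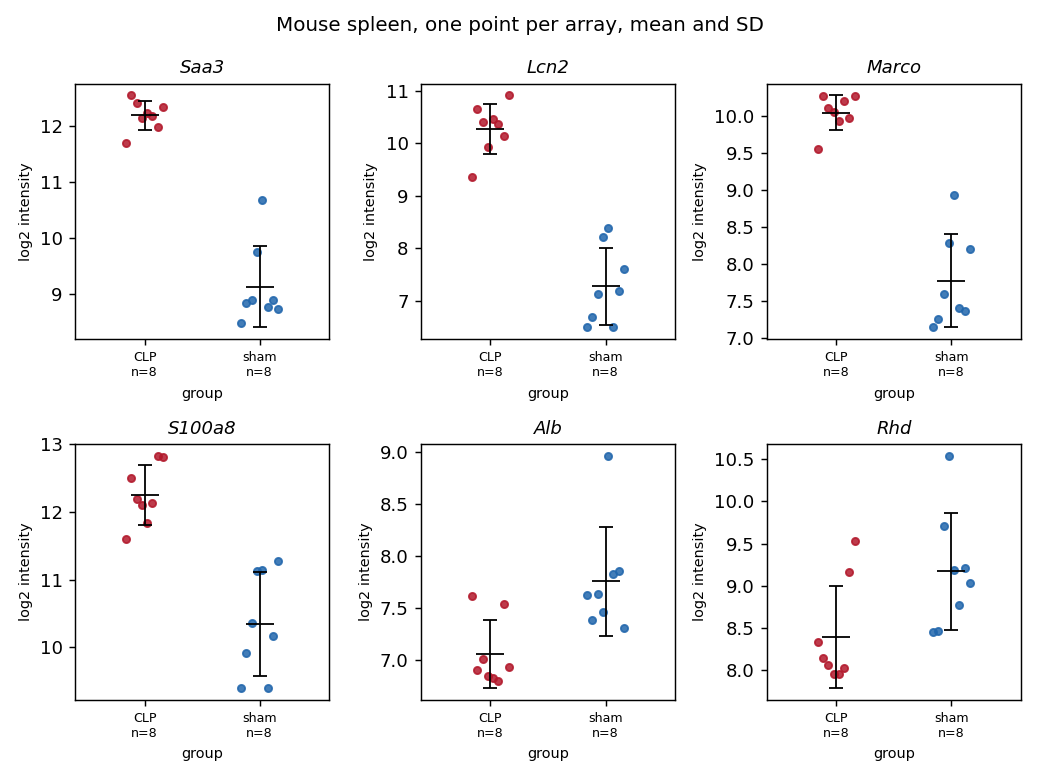
Levels of 6 genes in mouse spleen, with the group on the horizontal axis (8 CLP and 8 sham arrays) and log2 intensity on the vertical axis. Each point is 1 array and each bar a mean with its SD, and every CLP array lies above every sham array for Saa3, Lcn2, Marco and S100a8, while the Alb and Rhd groups overlap.

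Among myeloid lists in mouse spleen, 10 of 15 neutrophil granule genes rose and 0 fell (median 0.69, adjusted p = 0.0214), among them S100a9 by 1.61 and Lyz2 by 0.97. Of 19 monocyte and macrophage markers 13 rose (median 0.52, adjusted p = 0.00134), among them Msr1 by 0.64, the apoptosis inhibitor Cd5l by 1.21 and C1qb by 1.27, whose other probe set differed by −0.35. The neutrophil list had an adjusted p = 0.586 with an estimated correlation, and an adjusted p of 0.0727 without CLP replicate 7. Of 20 interferon-response genes 14 rose (median 0.38, adjusted p = 0.0028), with the immunity GTPases Ifi47 at 1.19, Gbp2 at 0.56 and Igtp at 0.34 and the peptide transporter Tap1 at 0.91. Of 14 innate sensing genes 8 rose (median 0.23, adjusted p = 0.0109), including Nfkbia, the NF-kappaB inhibitor, by 1.23 and the adaptor Myd88 by 0.48. Of 16 glucocorticoid-responsive genes 12 rose (median 0.51, adjusted p = 0.00128), with Cebpd at 1.45 and Anxa1 at 1.30. The innate sensing call was lost with quantile normalization, with the 50th percentile filter and with equal array spread (adjusted p up to 0.0966), the interferon call with that filter (0.056), and the neutrophil call with that filter and with array weights (up to 0.118). Apart from the neutrophil list, these lists had an adjusted p = 0.515 with an estimated correlation. Adjusted over the list alone, the same numbers of members rose in each of these 5 lists, and 1 neutrophil gene fell.

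Among stress and energy lists of the mouse spleen, 21 of 26 respiratory chain genes rose (median 0.46, adjusted p = 7.61e-05), with Ndufs3 at 0.89, Cox7a2 at 0.75 and Sdhc at 0.51. Of 15 glycolysis and hypoxia genes 11 rose and 1 fell (median 0.63, adjusted p = 0.00144), with Pgk1 at 1.11 and Pgam1 at 0.63, and with Bnip3, a mitochondrial cell death gene, at −0.50. Of 19 heat shock and unfolded protein response genes 13 rose (median 0.61, adjusted p = 0.00128), among them the chaperones Hspa5 by 1.44, Hspe1 by 1.26 and Hsp90aa1 by 1.08, while Hspd1 stood at 1.09 and −0.45 at its probe sets. These 3 lists had an adjusted p = 0.515 with an estimated correlation, and adjusted over the list alone 22, 11 and 13 members rose.

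Lymphoid lists of the mouse spleen went in different directions. Of 19 B cell markers 9 rose (median 0.39, adjusted p = 0.0477, and adjusted p = 0.7 with an estimated correlation), with Pou2af1, a coactivator in B cells, at 1.18 and the adaptor Blnk at 0.99. That call was lost with quantile normalization, the 50th percentile filter, equal array spread, the RNA quality covariate and matched arrays (adjusted p up to 0.209), and without any 1 of CLP replicates 3, 4 and 6 and sham replicates 1, 3, 6 and 7 (adjusted p of 0.0519 to 0.0861). Of 8 natural killer and cytotoxic markers 5 fell, among them Ctsw by 0.29 and Klrd1 by 0.24, and 1 rose, the granule protease gene Gzmb at 0.16 (median −0.24, adjusted p = 0.0109, and adjusted p = 0.515 with an estimated correlation). The cytotoxic call was lost with the 50th percentile filter and on matched arrays (adjusted p up to 0.0763). Of 18 erythroid genes 6 fell and all 18 were below 0 (median −0.26, adjusted p = 0.0028), including the alpha globin Hba-a1 by 0.35 and the membrane skeleton gene Ank1 by 0.40. Of 7 liver markers 5 fell (median −0.38, adjusted p = 0.0028), including Apoa2 by 0.38 and Ahsg by 0.41. The erythroid list had an adjusted p = 0.586 and the liver list an adjusted p = 0.515 with an estimated correlation. When adjusted over the list alone, 10 B cell markers rose, and 6 cytotoxic, 3 erythroid and 5 liver genes fell.

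The other 15 lists did not pass in mouse spleen. Their adjusted p was 0.573 for cytokines, plasma cells and T cells, 0.202 for MHC class II, 0.77 for platelets, apoptosis and stroma, 0.132 for cell cycle and acute-phase genes, 0.822 for complement and coagulation, 0.453 for endothelium, 0.246 for pancreas, 0.846 for adipocytes, 0.138 for skeletal muscle and 0.0685 for other granulocytes. Single members of these lists still moved, such as the iron oxidase gene Cp at 1.16, the protease inhibitor Serpina3n at 0.90 and the collagens Col4a1 at 1.65 and Col3a1 at 0.88. The T cell list had a mean of 0.06 and a median of −0.03, with Il7r at 0.52 and Ccr7 at 0.63 among 3 that rose and 3 others that fell. In the complement list the median was −0.05 and the mean 0.19, and in the adipocyte list −0.05 and 0.16.

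In all, 4226 of 8695 mouse spleen probe sets were called (48.6%), 2484 higher and 1742 lower. Of these 162 and 2 changed at least 2-fold, and 5018 probe sets had an unadjusted p under 0.05. The 3′ minus 5′ difference of the Gapdh control probe sets was 1.30 in CLP and 1.67 in sham (two-sided exact permutation p = 0.03, adjusted 0.18). That of the actin control probe sets was 1.77 and 2.25 (exact p = 0.0791, adjusted 0.286). The interquartile range of the arrays was 2.35 and 2.15 (exact p = 0.00746, adjusted 0.0953). With the mean of the Gapdh and actin differences as a covariate 1260 probe sets were called. All 16 named genes kept their call except Alb (−0.61, adjusted p = 0.0834) and 1110032A03Rik (−0.26, 0.306). With only the 7 CLP and 4 sham arrays of overlapping Gapdh difference 10 were called, among them Saa3 (2.65), Lcn2 (2.34), Marco (1.81) and Wfdc21 (1.32). Of the calls 58.8% were higher, against 40.3% after quantile normalization and 44.7% at equal array spread. With the floor at the 40th percentile the count was 2591, and with array weights 6555. The Rhd call was lost without any 1 of CLP replicates 1 to 6 or sham replicates 3, 4, 5 and 7, and that of 1110032A03Rik without any 1 of CLP replicates 3, 4 and 8 or sham replicates 1, 3, 6 and 7, with values of −0.77 to −0.56.

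In blood, CLP was first compared with sham. Cxcl13, a chemokine that attracts B cells, rose from 6.64 ± 0.29 (SD, n = 4) in sham, where 3 of 4 arrays were at the floor, to 10.58 ± 0.58 (n = 5) in CLP. The log2 difference was 4.00 ± 0.48 (SE, limma adjusted p = 3.38e-05), with values of 3.40 to 4.29 within the 4 batches that held both groups. Arg1, the enzyme arginase, rose by 3.77 ± 0.62 (adjusted p = 0.00052), Saa3 by 3.18 ± 0.46 (0.000196), Ifitm6 by 3.07 ± 0.39 (4.49e-05) and Lcn2 by 3.03 ± 0.38 (4.49e-05). Chil3, a chitinase-like protein of myeloid cells, rose by 2.98 ± 0.40 (9.53e-05), and the neutrophil and monocyte attractants Cxcl2 and Ccl2 by 2.91 ± 0.51 (0.001) and 2.85 ± 0.48 (0.000623). The falls were Mkrn1 (−1.10), the immunoglobulin light chain segments Igkv1-133 (−1.06) and Igkv6-23 (adjusted p = 0.0339), Cdr2 (−0.86), Ms4a1, the B cell surface protein CD20 (−0.75), Ces1d (−0.60), Trdmt1 (−0.58) and Lhx9 (−0.53), with adjusted p from 0.0136 to 0.0423. All 16 genes had the same direction in 4 of 4 batches.

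In CLP blood 9 of 17 neutrophil granule genes rose (median 1.22, 1.02 to 1.23 within batches, adjusted p = 1.22e-11, and adjusted p = 0.0988 with an estimated correlation), among them Fpr2, a receptor for formyl peptides, by 2.64 and Ngp by 2.10. Of 16 cytokine genes 8 rose (median 0.48, 0.34 to 0.52 within batches, adjusted p = 1.55e-05), including the interleukin-1 antagonists Il1rn by 1.44 and Il1r2 by 1.90, with another Il1r2 probe set at 2.32. Of 17 monocyte and macrophage markers 9 rose (median 0.74, 0.32 to 0.74 within batches, adjusted p = 8.06e-08), with Slc11a1 at 1.45, Msr1 at 1.40 and Fcgr1 at 0.76. Of 13 glucocorticoid-responsive genes 6 rose (median 0.45, 0.48 to 0.72 within batches, adjusted p = 1.01e-05), with Anxa1 at 2.42 and Cebpb at 1.84. These last 3 lists had an adjusted p = 0.158 with an estimated correlation. Adjusted over the list alone, 11 neutrophil, 9 cytokine, 13 macrophage and 8 glucocorticoid-responsive genes rose.

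Of 16 acute-phase, iron and metallothionein genes 6 rose in CLP blood (median 0.91, 0.31 to 1.72 within batches, adjusted p = 1.3e-06, and adjusted p = 0.17 with an estimated correlation), including Saa2 by 1.87, the metallothionein Mt2 by 1.32 and the protease inhibitor Slpi by 0.86. The mean of the liver marker list, which shares the hemopexin gene Hpx with this list, lay between −1.06 and −0.76 on 18 arrays of batches 1 to 3, between 0.21 and 2.14 on the 14 arrays of batches 4 and 5, and at 2.12 on CLP+ABX replicate 1 of batch 1. After CLP 5 of 19 interferon-response genes rose (median 0.33, 0.14 to 0.33 within batches, adjusted p = 0.00555, and adjusted p = 0.363 with an estimated correlation), with Ifit1 at 1.04, Usp18 at 0.93 and Irf7 at 0.79.

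**Figure D2:**
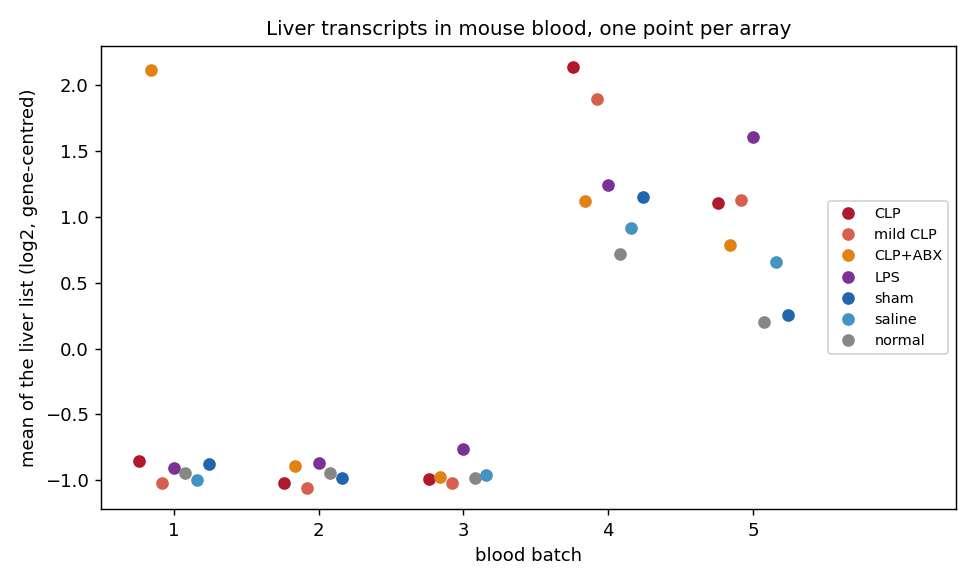
Mean of the liver marker list in each of the 33 blood arrays, as log2 intensity centred per gene on the vertical axis, with the 5 batches on the horizontal axis and groups by colour. Each point is 1 array, and the arrays of batches 4 and 5 lie between 0.21 and 2.14, while those of batches 1 to 3 lie between −1.06 and −0.76 apart from 1 CLP+ABX array at 2.12.

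Of 17 heat shock and unfolded protein genes 1 rose, Hspa5 by 1.37, and of 15 glycolysis genes 3, with Tpi1 at 1.15 and Hif1a at 0.68 (both lists at an adjusted p = 0.00879, with batch medians of 0.19 to 0.30 and 0.11 to 0.34, and an adjusted p = 0.241 and adjusted p = 0.253 with an estimated correlation). Of 26 respiratory chain genes 3 rose (median 0.18, 0.15 to 0.26 within batches, adjusted p = 0.043, and adjusted p = 0.425 with an estimated correlation). As lists, B cell markers were lower (median −0.09, −0.30 to 0.08 within batches, adjusted p = 0.00464, and adjusted p = 0.17 with an estimated correlation), with none of the 16 members called and Cd79a at −0.43. The 12 MHC class II genes were lower (median −0.08, −0.30 to 0.18 within batches, adjusted p = 0.041, and adjusted p = 0.363 with an estimated correlation), although the only member called, the antigen-processing protease Ctss, rose by 0.76. The 12 endothelial markers tested lower, with a mean of −0.05 and a median of 0.01 (−0.11 to 0.03 within batches, adjusted p = 0.043, and adjusted p = 0.158 with an estimated correlation). These lists were tested against the other genes, and the median over all probe sets in this comparison was 0.0546. When adjusted over the list alone, 10 acute-phase, 9 interferon, 6 heat shock, 6 glycolysis and 3 respiratory chain genes rose, and 0 B cell or endothelial genes passed.

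In all, 513 blood probe sets were called between CLP and sham, 492 higher (95.9%) and 21 lower. Of these 123 and 3 changed at least 2-fold, and 1722 probe sets had an unadjusted p under 0.05. Without the batch block 190 were called, and after quantile normalization 81.7% of the calls were higher. The interquartile range of the arrays was 2.10 in CLP and 2.01 in sham (two-sided exact permutation p = 0.0159, adjusted 0.127, arrays relabelled across batches). The count was 308 without CLP replicate 5, 323 without CLP replicate 4, 292 without CLP replicate 3 and 169 without sham replicate 1. None of the 8 named rises was lost without any single array, while leaving out any 1 of the 9 arrays ended at least 1 of the 8 named falls, at log2 values of −1.11 to −0.37. The respiratory chain list was lost with quantile normalization, the 50th percentile filter and equal array spread, and without any 1 of CLP replicates 3, 4 and 5 and sham replicates 1, 2 and 5 (adjusted p of 0.0569 to 0.187). The MHC class II list was lost without CLP replicate 1 or 3 or sham replicate 2, 4 or 5 (0.0617 to 0.196), and the endothelial list without CLP replicate 2, 3 or 4 or sham replicate 4 or 5 (0.0613 to 0.0874). The MHC class II list was also lost with quantile normalization, without the filter on dim probe sets and without the batch block (up to 0.21). The endothelial list was lost with quantile normalization, without the filter, with the 50th percentile filter, with the floor at the 40th percentile and in a fit of these groups only (up to 0.176), and the glycolysis list with that floor (0.0523).

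**Figure D3:**
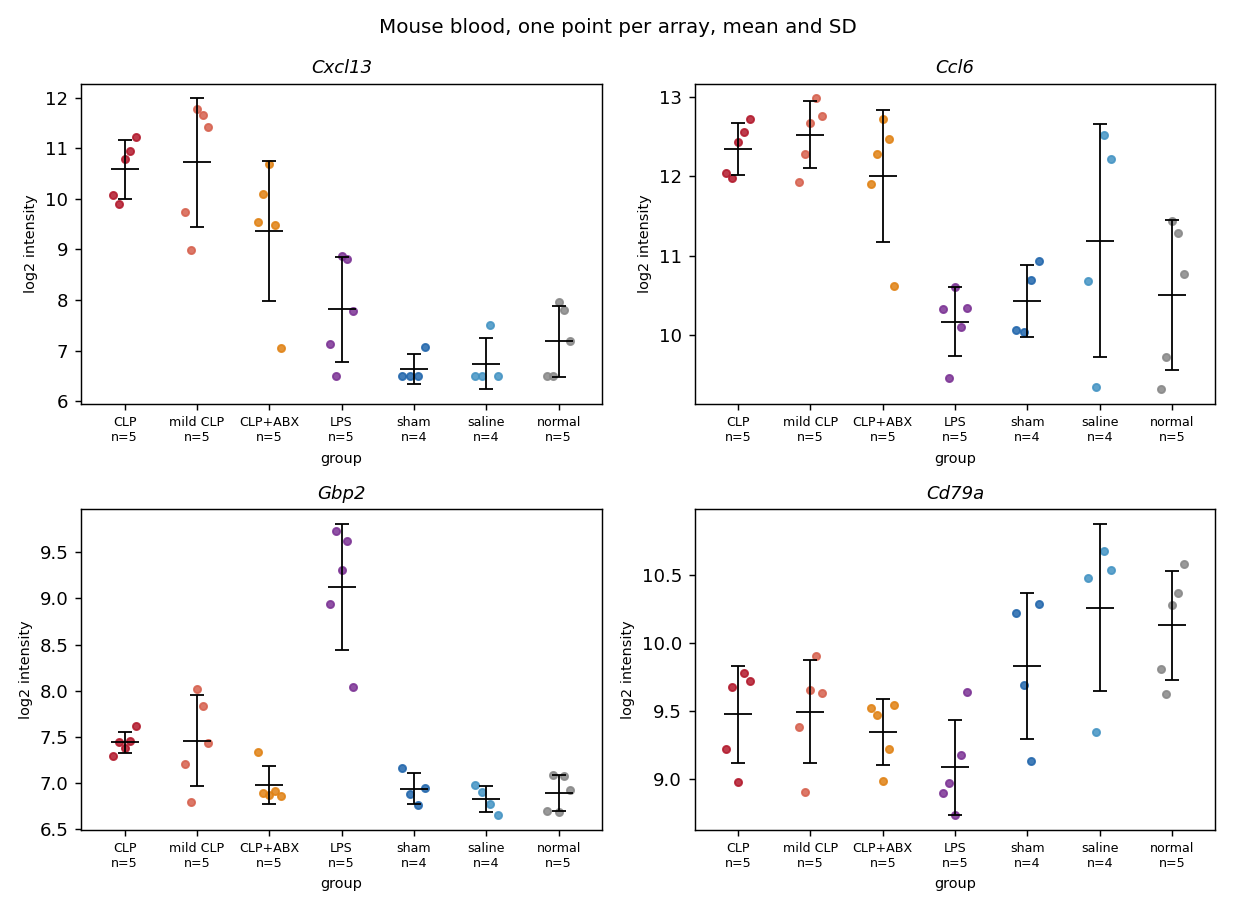
Levels of 4 genes in mouse blood, with the 7 groups on the horizontal axis and log2 intensity on the vertical axis. Each point is 1 array and each bar a mean with its SD, with Cxcl13 at 10.58 in CLP against 6.64 in sham and Gbp2 at 9.13 in LPS against 6.82 in saline.

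LPS was compared with its own control, saline. Gbp2, an interferon-induced GTPase, rose from 6.82 ± 0.14 (SD, n = 4) to 9.13 ± 0.68 (n = 5), a difference of 2.26 ± 0.22 (SE, limma adjusted p = 1.17e-06, and 1.39 to 2.75 within batches). Lcn2 rose by 3.00 ± 0.38 (5.38e-05), Saa3 by 2.44 ± 0.46 (0.00343), Fpr2 by 2.39 ± 0.34 (0.000266), S100a9 by 2.33 ± 0.39 (0.00122), S100a8 by 2.29 ± 0.32 (0.000266), Chil3 by 2.28 ± 0.40 (0.00181) and Il1r2, a decoy receptor for interleukin-1, by 2.17 ± 0.37 (0.00149).

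The largest falls after LPS were those of Car2, a red cell carbonic anhydrase (−2.06 ± 0.34, adjusted p = 0.00106), Mkrn1 (−1.80, 0.000777), Pabpc1, which binds poly(A) tails (−1.78 ± 0.22, 5.38e-05), Alox15 (−1.77, 0.0198), Yipf4 (−1.68, 0.00256), the red cell anion exchanger Slc4a1 (−1.64, 0.012), Mxi1 (−1.63, 0.0134) and C1qa, a chain of complement C1q (−1.62 ± 0.38, 0.0199). All 16 genes had the same direction in 4 of 4 batches. Slc4a1 was no longer called without saline replicate 5 (−1.17) or 1 (−1.39), Mxi1 without saline replicate 5 (−1.08) or 1 (−1.56), Alox15 without LPS replicate 2 (−1.56) or saline replicate 1 (−1.44), and C1qa without LPS replicate 2 (−1.56) or 3 (−1.41) or saline replicate 1 (−1.25) or 3 (−1.57).

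After LPS, 8 lists passed with both correlations. Of 19 interferon-response genes 8 rose and 1, the exonuclease gene Isg20, fell by 0.64 (median 0.52, 0.07 to 0.73 within batches, adjusted p = 1.5e-15 and 0.0274 with an estimated correlation), with Cxcl9, a chemokine induced by interferon gamma, at 0.86, Ifit3 at 0.92 and Irf7 at 0.85. Of 17 neutrophil genes 7 rose (median 0.71, 0.07 to 1.40 within batches, adjusted p = 1.58e-10 and 0.034), and of 16 cytokine genes 3 (0.09 to 0.38 within batches, adjusted p = 1.31e-07 and 0.0456), with the chemokine Ccl5 at 1.35. Of 13 glucocorticoid-responsive genes 3 rose (0.11 to 0.53 within batches, adjusted p = 8.51e-09 and 0.0274), namely Il1r2, which is also in the cytokine list, and Mt1 and Mt2, which are also in the next list. Of 16 acute-phase, iron and metallothionein genes 3 rose (adjusted p = 1.5e-11 and 0.0428, with batch medians of 0.36 to 1.40), with Mt1 at 2.06 and Mt2 at 1.45. Of 12 MHC class II genes 4 fell (median −0.35, −0.58 to −0.22 within batches, adjusted p = 3.15e-08 and 0.0274), namely H2-Aa by 1.43 ± 0.28, Cd74 by 1.24, H2-Ab1 by 0.91 and H2-Eb1 by 0.71.

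Of 16 B cell markers 2 fell after LPS (median −0.24, −0.36 to −0.13 within batches, adjusted p = 2.81e-07 and 0.0274 with an estimated correlation), the antigen receptor subunit Cd79a by 1.23 ± 0.21 and Ighm by 0.69, whose 8 other probe sets ran from −0.74 to 0.01. Of 17 erythroid genes 4 fell (median −0.15, −0.14 to −0.07 within batches, adjusted p = 0.000338 and 0.0428), among them Epb42 by 0.79 and Rhd by 0.38. Adjusted over the list alone, 11 interferon, 10 neutrophil, 5 cytokine, 5 glucocorticoid-responsive and 7 acute-phase genes rose, and 8 MHC class II, 8 B cell and 5 erythroid genes fell.

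With the preset correlation only, monocyte and macrophage markers were lower (2 of 17 fell, C1qa and Cd5l by 1.22, and 6 adjusted over the list alone, with batch medians of −0.56 to 0.04 and a fall in 2 of 4 batches, adjusted p = 0.0202 and adjusted p = 0.592 with an estimated correlation). Pancreatic markers (adjusted p = 0.0193, and adjusted p = 0.122 with an estimated correlation) and liver markers (adjusted p = 0.0263, and adjusted p = 0.636 with an estimated correlation) were higher with no member called. The macrophage call was lost without LPS replicate 2 or 3 or saline replicate 1 or 3 (adjusted p of 0.0635 to 0.246), the pancreatic call without LPS or saline replicate 4 (0.113 to 0.146), and the liver call without LPS replicate 3 or 5 or saline replicate 1 or 4 (0.0679 to 0.267). Without the batch block or with the RNA quality covariate the macrophage and liver calls were lost. The liver call was also lost with quantile normalization, the 50th percentile filter and array weights (up to 0.538). The pancreatic call was lost with array weights. Batch medians ran from −0.01 to 0.60 for pancreatic and from 0.06 to 0.48 for liver markers. In all, 158 probe sets were called, 51 higher (32.3%) and 107 lower, with 40.4% higher after quantile normalization and 48.5% with the RNA quality covariate. Of the 158 calls 33 higher and 45 lower ones changed at least 2-fold, and 906 probe sets had an unadjusted p under 0.05. The count was 105 without the filter on dim probe sets, 346 with array weights, 35 without the batch block, 67 in a fit of these groups only, 103 without LPS replicate 4 and 72 without saline replicate 1.

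The response to CLP, relative to sham, was then set against the response to LPS, relative to saline, in 1 contrast. The CLP response exceeded that to LPS by 2.55 ± 0.39 (log2, SE) for Errfi1, an inhibitor of epidermal growth factor receptors (limma adjusted p = 0.00605), by 3.50 ± 0.66 and 3.02 ± 0.56 for the chemokines Ccl9 and Ccl6 (both 0.0238), by 3.08 ± 0.68 for Cxcl13 and by 2.44 ± 0.54 for C1qa (both 0.0483). The LPS response was larger for Gbp2 (−1.70 ± 0.31, 0.0238) and Cxcl9 (−1.08 ± 0.21, 0.0273). A difference here can come from a rise after CLP, a fall after LPS, a difference between the sham and saline controls, or several of these. C1qa was among the largest falls after LPS, and the CLP effect alone was 1.46 for Errfi1 and 2.46 for Ccl9. Ccl6 stood at 12.52 and 12.22 on saline replicates 1 and 3, within its CLP range of 11.98 to 12.73. On saline replicates 4 and 5 it was at 10.68 and 9.339. For Cxcl13, 3 of 4 sham and 3 of 4 saline arrays were at the floor, so its difference is not exact. Other genes with a larger CLP response included the macrophage marker Adgre1 (1.57, 0.0407), the lysosomal proteases Ctsc (1.60), Ctsb (1.11) and Lgmn (1.05), and the complement receptor C3ar1 (0.77), which were singled out after their values were seen.

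Of 17 monocyte and macrophage markers 2, Adgre1 and C1qa, passed over all genes and 14 adjusted over the list alone (median 1.14, adjusted p = 9.69e-11, and adjusted p = 0.157 with an estimated correlation). In the 3 batches with all 4 groups this median was 1.02, 0.36 and 0.54. The 19 interferon-response genes were lower as a list (median −0.07, mean −0.17, adjusted p = 0.00192, and adjusted p = 0.527 with an estimated correlation), with Gbp2 and Cxcl9 the only members called, both over all genes and adjusted over the list alone. Without CLP replicate 1 that list had an adjusted p of 0.072, and with the 50th percentile filter 0.0948. The median over all probe sets in this contrast was 0.0924.

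In all, 24 probe sets were called, 22 higher (91.7%) and 2 lower, with 1250 at an unadjusted p under 0.05. The count was 8 after quantile normalization (75% higher), 1 without the filter on dim probe sets, 12 with a 50th percentile filter, 7 with the floor at the 40th percentile, 104 with array weights, 2 without the batch block and 5 with the RNA quality covariate. It was 1 without CLP replicate 5, saline replicate 1 or sham replicate 1, 2 without CLP replicate 2 or 4 or LPS replicate 2 or 4, and 3 without sham replicate 5. It was 6 without CLP or LPS replicate 3, 8 without LPS replicate 1, 11 without saline replicate 3, 12 without sham replicate 2, 76 without saline replicate 4, 99 without LPS replicate 5 and 118 without CLP replicate 1. Errfi1 kept its call without any single array, while all except CLP replicate 1, LPS replicate 5 and replicate 4 of saline and sham ended at least 1 of the other 6 calls, with adjusted p up to 0.161.

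Mild CLP and CLP+ABX were each compared with sham. The 5 largest rises after mild CLP were Cxcl13 (4.14 ± 0.48, limma adjusted p = 3.51e-05), Arg1 (4.02), Saa3 (3.22), Cxcl2 (3.04) and Ifitm6 (3.04), and the 5 largest falls Mkrn1 (−1.03), Dcaf12 (−0.79), Ms4a1 (−0.65), Col8a1 (−0.57) and Ces1d (−0.54), the last 2 in 3 of 4 batches. After CLP+ABX the largest rises were Arg1 (3.09, 0.00735), Cxcl13 (2.79, 0.00273), Saa3 (2.65, 0.00299), Wfdc21 (2.45) and Ifitm6 (2.31). The only falls called were Pla2g2c, a secreted phospholipase (−0.59, 0.0161), and the light chain segment Igkv4-68 (−0.37, 0.0497). The SD of Saa3 was 1.15 in the CLP+ABX group and 0.05 in the CLP group.

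After mild CLP, 11 lists were higher and 3 lower with the preset correlation. Among them 10 of 17 neutrophil genes rose (adjusted p = 2.84e-10), with Ngp at 2.13, as did 11 of 17 macrophage markers (4.51e-08), with Msr1 at 1.59, 7 of 16 cytokine genes (4.08e-06), with Il1rn at 1.36, and 8 of 13 glucocorticoid-responsive genes (1.38e-05), with Anxa1 at 2.54. The others were 5 of 19 interferon-response (0.000958), 3 of 14 innate sensing (0.0321), 6 of 17 heat shock (0.00209), 8 of 16 acute-phase (3.49e-06), 4 of 15 glycolysis (0.00908), 6 of 26 respiratory chain and 4 of 14 complement and coagulation genes (both 0.0326). The B cell, cell cycle and endothelial lists were lower (all 0.0338), with 1 member called, the B cell transcription factor Pax5 at −0.28. The lowest of these lists' values was adjusted p = 0.11 with an estimated correlation. When adjusted over the list alone, 11 neutrophil, 15 macrophage, 12 cytokine and 8 glucocorticoid-responsive genes rose.

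After CLP+ABX, 8 of 17 neutrophil genes rose (adjusted p = 1.16e-09), with Fpr2 at 1.97, 3 of 17 macrophage markers (0.000269), with Slc11a1 at 1.07, 3 of 16 cytokine genes (0.00108), with Ccl2 at 2.28, 4 of 13 glucocorticoid-responsive (0.000192), 4 of 16 acute-phase (2.4e-08) and 3 of 26 respiratory chain genes (4e-04), with Uqcrb at 0.63. The B cell list was lower (0.00108) and the liver list higher (0.0181), with 0 members called in either. The lowest value among these lists was adjusted p = 0.195 with an estimated correlation. Batch medians ran from 0.24 to 3.24 in the acute-phase list and from −0.07 to 3.37 in the liver list, whose call was lost without CLP+ABX replicate 1 (adjusted p = 0.538) or sham replicate 5 (0.108). Adjusted over the list alone, 11 neutrophil, 6 macrophage, 5 cytokine, 7 glucocorticoid-responsive, 13 acute-phase and 9 respiratory chain genes rose.

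At an unadjusted p under 0.05 there were 2011 probe sets for mild CLP and 1308 for CLP+ABX. Mild CLP gave 832 calls, 798 higher (95.9%, or 76.5% after quantile normalization) and 34 lower, and CLP+ABX gave 241, 239 higher (99.2%, or 79.5% after quantile normalization) and 2 lower. The interquartile range of the arrays was 2.08 in mild CLP and 2.01 in sham (two-sided exact permutation p = 0.00794, adjusted 0.0953). In CLP+ABX it was 2.08 (exact p = 0.0714 against sham, adjusted 0.286). The mild count was 367 without the batch block, 365 in a fit of these groups only, 1267 without mild CLP replicate 5, 490, 469 and 550 without mild CLP replicates 1, 2 and 3, and 330 without sham replicate 1. The CLP+ABX count was 129 without the filter on dim probe sets, 94 with array weights, 154 with 1 probe set per gene, 47 without the batch block, 72 in a fit of these groups only, 83, 150, 53 and 547 without CLP+ABX replicates 4, 5, 1 and 2, and 38 and 154 without sham replicates 1 and 2. Each of the 5 mild CLP falls was lost without at least 1 of the 9 arrays, and each array ended at least 1 of them (log2 values of −1.04 to −0.42). Arg1 was lost in CLP+ABX without sham replicate 1 (2.65, adjusted p = 0.0642), Pla2g2c without CLP+ABX replicate 1 or sham replicate 1 or 2, and Igkv4-68 without 7 of the 9 arrays. In mild CLP, the lists lost without single arrays were B cell (without mild CLP replicate 3 or 5 or sham replicate 2 or 4, adjusted p up to 0.146), cell cycle (mild CLP replicate 2 or 5, sham replicate 2 or 4, up to 0.0695), endothelial (mild CLP replicate 1 or 5, sham replicate 4 or 5, up to 0.0661), complement and coagulation (sham replicate 4, 0.0661), innate sensing (mild CLP replicate 1, sham replicate 4, up to 0.066) and respiratory chain (mild CLP replicate 2 or 5, sham replicate 1, up to 0.0943). With quantile normalization or the 50th percentile filter the cell cycle, endothelial, complement and respiratory chain calls were lost. The cell cycle and B cell calls were lost without the batch block and in a fit of these groups only, which also ended the innate sensing call. Array weights ended the endothelial and respiratory chain calls, the floor at the 40th percentile the cell cycle call, and leaving out the filter the complement call. In CLP+ABX the liver call was lost with the 50th percentile filter, with array weights and without the batch block. Every list that passed had batch medians of 1 sign in 4 of 4 batches, except the B cell list of both comparisons and the liver list of CLP+ABX with 3 of 4.

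Between mild CLP and CLP the lowest p were those of the neutrophil attractant Cxcl1 (0.38), Tmed9, Foxn3, Psmb3 and Phox2a among higher genes and Myl10 (−0.40), Neo1, Htt, Abhd8 and Slc4a2 among lower ones, all at an adjusted p of 1. Between CLP+ABX and CLP they were Mrpl16 (0.28), Rps4l, Lgals8, Ilrun and Rfc5 higher and Pla2g2c (−0.52), Pimreg (−0.41), Gdf5, Atg2a and Gstm3 lower, all at an adjusted p of 0.574. In each comparison limma called 0 probe sets, with 94 and 751 at an unadjusted p under 0.05, where 435 were expected by chance.

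As lists, 5 were lower in CLP+ABX than in CLP, namely neutrophil genes (adjusted p = 0.0325, with Ngp at −0.77), cytokines (0.0371, with Il1b at −0.73), interferon response (0.0325, with Irf7 at −0.45), macrophage markers (0.0179, with Csf1r at −0.33) and glycolysis (0.0371, with Pfkp at −0.24). None of their members passed over all genes or adjusted over the list alone, and each had an adjusted p = 0.762 with an estimated correlation. Batch medians crossed 0 in all 5, from −1.44 to 0.14 for neutrophil genes and from −0.76 to 0.19 for macrophage markers. Removing CLP replicate 3 or CLP+ABX replicate 2 ended each of these calls (adjusted p of 0.0751 to 0.143). Calls were also lost without CLP+ABX replicate 3 (all but interferon, 0.275 to 0.653), CLP replicate 1 (glycolysis, cytokines and neutrophil, 0.0557 to 0.262), CLP replicate 5 (glycolysis and neutrophil, 0.0542 to 0.0915), CLP replicate 2 (interferon, 0.0547), and CLP+ABX replicates 1 (interferon, 0.142) and 5 (cytokines, 0.0654). Array weights ended the neutrophil, cytokine and glycolysis calls, as did a fit of these groups only. The floor at the 40th percentile ended the cytokine, interferon and glycolysis calls, the 50th percentile filter the interferon and glycolysis calls, leaving out the filter the cytokine call, and leaving out the batch block the glycolysis call.

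Both control procedures were set against normal blood. After the sham operation the genes of lowest p included Cox6c, a respiratory chain subunit (−1.10, adjusted p = 0.672), Zfand6 (−0.79), Eloc and Dock2, at the same adjusted p, and Paip2 (−0.76, 0.893) among lower genes and Recql5 (0.29, 0.955), Ptpn9, Selenos, Celf1 and Anp32a among higher ones. After saline they were Epc1 (−0.38), Dhrs7b, Ctse, Ilrun and Dhx15 lower and Setd4 (0.47), Ap3s2, Ltc4s, Oc90 and Ifi30 higher, all at an adjusted p of 0.958. In both comparisons limma called 0 probe sets and no list passed with all blood arrays fitted together, with 403 and 392 probe sets at an unadjusted p under 0.05.

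The series set out to build a classifier of sepsis, so the 15 infected blood arrays were compared with the 18 not infected, which included LPS. Cxcl13 was higher by 3.10 ± 0.25 (SE, limma adjusted p = 6.78e-09, 2.74 to 3.37 within batches). Arg1 was higher by 2.53, Ifitm6 by 2.22, Ccl2, Lcn2 and Saa3 by 2.19, 2.19 and 2.14, Wfdc21 by 2.13 and Ghrl, the gene of the hormone ghrelin, by 2.04 (6.78e-09, with its other probe set at −0.02). Cdr2 fell by 0.89 (2.18e-05), Nusap1 by 0.85, Rnf11 by 0.77, Mkrn1 by 0.76, Fam220a by 0.75, Dcaf12 by 0.74, Ccl5, a chemokine of T and natural killer cells, by 0.67 (0.0047) and Igkv1-133 by 0.65. All 16 went the same way in 5 of 5 batches, and none lost its call in any of 33 fits without 1 array. Ccl5 rose after LPS, which is part of the not infected mean, so part of its difference can come from LPS blood.

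Of 17 neutrophil genes 12 rose in infected blood (median 0.92, 0.68 to 1.04 within batches, adjusted p = 1.79e-09), with the collagenase Mmp8 at 1.34 and Fpr2 at 1.76, and of 17 macrophage markers 14 (median 0.47, 0.36 to 0.66 within batches, 6.57e-07), with Slc11a1 at 1.07 and Fcgr1 at 0.65. Of 16 acute-phase genes 12 rose (median 0.82, 0.25 to 1.43 within batches, 1.65e-07), of 16 cytokine genes 9 rose and Ccl5 fell (1.53e-05), and of 13 glucocorticoid-responsive genes 8 rose (3.06e-05), with Anxa1 at 1.98. Of 17 heat shock genes 9 rose (0.00847), of 26 respiratory chain genes 11 rose and Ndufa1 fell (0.0211), of 15 glycolysis genes 7 rose (0.0266) and of 14 complement and coagulation genes 9 (0.00413), with the calcium-dependent membrane protein Anxa2 at 1.21. The B cell list was lower (0.00413), with Pou2af1, Cd79a and Pax5 called lower and Ly86 higher, and so was the natural killer list (0.0422), with Klra3, Gzma and Fasl called. The lowest value among these lists was adjusted p = 0.196 with an estimated correlation. When adjusted over the list alone, 12 neutrophil, 14 macrophage, 14 acute-phase, 9 cytokine, 8 glucocorticoid-responsive, 9 heat shock, 13 respiratory chain, 7 glycolysis and 9 complement genes rose, and 3 B cell and 3 natural killer genes fell.

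In all, 1891 probe sets were called in infected blood, 1348 higher (71.3%, or 43.5% after quantile normalization) and 543 lower. Of these 71 and 0 changed at least 2-fold, and 3000 probe sets had an unadjusted p under 0.05. Without the batch block 937 were called. The glycolysis list was lost without CLP replicate 5 (adjusted p = 0.0533) and with the 50th percentile filter (0.0544). The natural killer list was lost with quantile normalization, the 50th percentile filter, the floor at the 40th percentile, equal array spread and no batch block (up to 0.218), and without any 1 of CLP replicates 4 and 5, CLP+ABX replicates 1 and 5, mild CLP replicate 2, LPS replicate 5, normal replicates 1 and 3, saline replicate 4 and sham replicate 2 (0.0519 to 0.0773).

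A diagonal linear discriminant on 50 probe sets, trained on 4 batches and tested on the one left out, placed 30 of 33 blood arrays in their class. In 100 permutations of the labels within batches the median was 17 and the highest 25, for p = 0.0099, the smallest they can give (one-sided permutation test). The 3 arrays misplaced were CLP+ABX replicates 2 and 3 and LPS replicate 5. Genes used in all 5 training sets were Cxcl13, Anxa1, Mmp8, Pirb, an inhibitory receptor of myeloid cells, the Fc receptor chain Fcer1g, Manf, Ctsz and Ostc, together with 4 probe sets of no single gene. With LPS as a class of its own, 31 of 33 arrays were placed correctly, with all 5 LPS arrays, 13 of 13 controls and 13 of 15 infected arrays.

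The spleen response was then followed into blood with a score, the mean of the 50 probe sets of lowest p among those higher in CLP spleen minus that of the 50 among those lower. It was 0.29 ± 0.20 (SD, n = 15) in infected and −0.25 ± 0.21 (n = 18) in not infected blood, a difference of 0.54 (two-sided permutation test within batches, p = 1e-05, the smallest that 100000 permutations can give), and 12 of 15 infected arrays lay above all not infected arrays. By group the means were 0.30 ± 0.13 for CLP, 0.41 ± 0.12 for mild CLP, 0.17 ± 0.27 for CLP+ABX and 0.04 ± 0.15 for LPS, and −0.39, −0.37 and −0.32 for sham, saline and normal. Pairs of groups were compared by two-sided exact permutation tests, adjusted over 7 comparisons, which relabelled arrays freely across batches. Relabelling within 4 or 5 batches cannot pass 0.05. LPS exceeded saline by 0.41 (exact p = 0.0159, adjusted 0.0278) and CLP exceeded LPS by 0.26 (exact p = 0.0159, adjusted 0.0278), in 4 of 4 and 5 of 5 batches. CLP exceeded sham by 0.68 and mild CLP by 0.80 (both exact p = 0.00794, adjusted 0.0278), and CLP+ABX by 0.56 (exact p = 0.0238, adjusted 0.0333), each in 4 of 4 batches. CLP+ABX and CLP differed by −0.13 (exact p = 0.325) and mild CLP and CLP by 0.11 (exact p = 0.198).

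**Figure D4:**
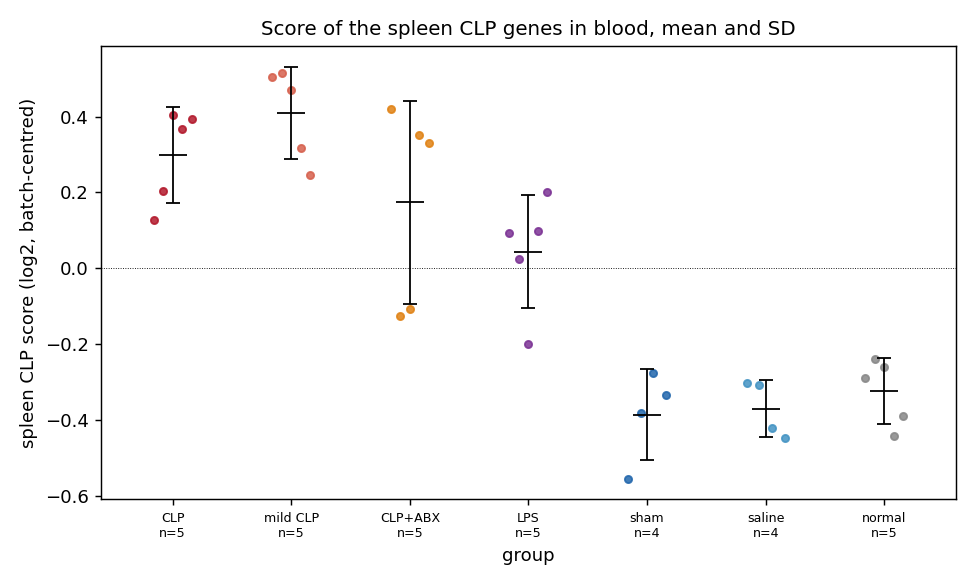
Score of the spleen CLP genes in each blood array, with the 7 groups on the horizontal axis and the batch-centred log2 score on the vertical axis. Points are arrays and bars means with SD, with mild CLP highest at 0.41, LPS at 0.04 and the 3 control groups between −0.39 and −0.32.

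Calls were also compared between conditions. Of 8695 blood probe sets 38 were higher in both CLP and LPS, where independent lists of these sizes would share 2.89, and 6 were lower in both, against 0.258. The contrasts used different control groups, and their errors had a design correlation of −0.00531. Across probe sets, which are not independent replicates, the fold changes had a Pearson r of 0.41. Between CLP blood and CLP spleen 316 of 7514 probe sets were higher in both, against 128 if independent, and 2 were lower in both, against 3.67, with r = 0.46. In opposite directions 16 were higher in blood and lower in spleen, against 94.1. Between LPS blood and CLP spleen 40 were higher in both (13.6 if independent) and 6 lower in both (21), with r = 0.08, and 29 were lower in LPS blood and higher in spleen (28.6). Of genes with the same symbol in human and mouse, 813 were called in mouse spleen, and 55.6% of them (452) had the same sign in human spleen. With 100 relabellings of the human arrays that share ran from 29.2% to 67.9% (two-sided permutation p = 0.65), and the correlation across 1621 genes was 0.12 (permutation p = 0.6).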

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

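The tests of mislabelled arrays, of a lower share of lymphocytes, of batches and of red cell share, and those with the RNA quality covariate, matched arrays, a common ceiling or equal array spread, and the exchanges within batches for the CLP minus LPS contrast, were chosen only after the result was seen.

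In mouse spleen the breadth of the change after CLP was weighed, since the groups differed in mean RNA quality and array spread. Of the 164 calls of at least 2-fold, 84.15% were kept with the RNA quality covariate (median log2 size 1.13 before, 0.8 in the same direction after, median SE 0.23 and 0.19) and 100% at equal array spread, which argues against either as their whole cause. Of the 4062 smaller calls 85.33% were kept at equal spread but 24.2% with the covariate, with the median going from 0.336 to 0.223 and its SE from 0.0979 to 0.0926, so RNA quality and the operation cannot be told apart for these. On arrays matched for RNA quality 5 calls of each kind were kept, with fewer arrays and an SE of 0.257 and 0.123. The medians were 0.788 and 0.231, near those with the covariate. Both settings thus gave smaller changes than the main fit, and what part of this comes from RNA quality was not tested. The groups overlapped on the first principal component, and mislabelled arrays were weighed as a cause of that overlap. Of the CLP arrays, 0 of 8 lay in the sham range of the mean of the neutrophil and acute-phase lists (0.0991 to 0.557 in CLP, −0.442 to −0.0644 in sham). That test decides nothing, since genes of these lists were already known to part the groups. Mislabelled arrays stay open as a cause of the overlap. For the breadth of the change, a response of the spleen to CLP stays open.

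In human spleen the lower lymphocyte and MHC class II lists and the higher neutrophil list were weighed. Leaving out septic replicate 6, an array apart from the rest, kept 5 of the 6 list calls, which argues against that array as the cause. A common array ceiling of 21626.8 kept 6 of 6. It changed only 182 probe sets, so it argues against the brightest values as the cause. Other effects of the differing array maxima, which ran from 21627 to 64592, were not tested. A lower share of lymphocytes in septic spleens stays open. It would raise the lists of other cell types alike, and the neutrophil list exceeded the mean of the macrophage, endothelial and stroma lists by 0.199 more in septic than in injured spleens (two-sided exact permutation p = 0.2386), which decides nothing. Sepsis itself also stays open, untested.

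In blood the larger macrophage response to CLP than to LPS was weighed. For a batch difference, the list median was above 0 in 3 of 3 batches that held all 4 groups (1.02, 0.356 and 0.535). The pattern was thus not confined to 1 batch. These values cannot decide on a batch difference as its cause, since the list was picked for this contrast on the same arrays. A lower share of red cell RNA in LPS blood was tested by the neutrophil list minus the macrophage list, which was 1.25 higher in LPS than in saline blood (two-sided exact permutation p = 0.007937). That test decides nothing, since such a share would raise macrophage genes after LPS and both lists had been called before. A different macrophage response to CLP and to LPS stays open as a hypothesis, found and tested on the same data. So does a difference between the saline and sham controls, which was not tested. In a fit of saline and normal arrays only, the macrophage list was higher in saline blood.

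Other splits of the samples were fitted, 100 for each comparison with the real one included. In mouse spleen 1 split, the real one, called as many probe sets (4226, highest other 3221). The same held in infected blood (1891, highest other 1016, labels exchanged only within batches). In each, 3 other splits called any probe set. A share of 1 in 100 argues against chance for both, if the arrays are independent samples, which the labels do not state. The splits of the other blood comparisons ignored the batches, in which arrays were alike (mean correlation 0.459). Of these, 1 reached the real count for LPS (158, highest other 106), 2 for CLP (513, highest other 667, a near mirror image that moved 8 of 9 samples), 2 for mild CLP (832, highest other 928, with 2 samples exchanged) and 3 for CLP+ABX (241, highest other 590, with 8 of 9 moved, and 303 with 2 exchanged). Exchanges within batches give 16 splits for each, too few for a share under 0.05, with a highest other count of 0 for CLP and mild CLP, 1 for LPS and 193 for CLP+ABX.

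For the CLP minus LPS contrast 2 of 100 splits reached the real count of 24. The other one, which moved 10 of 18 samples, called 70, and the cause of that count was not tested. Of 100 exchanges within batches 3 reached the real count, the other 2 with 250 and 97 calls. Both left all 4 CLP pairs in place and so kept the CLP effect, which makes these counts no test of the difference, and whether chance can be excluded stays open.

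Where the real count was 0, all 100 splits reached it by construction, so they test nothing. The highest other count was 315 in human spleen, 4 in mild CLP against CLP, 2 in CLP+ABX against CLP, 1 in sham against normal and 2 in saline against normal. The cause of the 315 calls was not tested.

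Single arrays stood apart from their group in 6 of 138 list scores and 10 of 138 gene levels, and chance gives about 1 in 20. The values are the gap to the nearest array as a share of the group's range. Among list scores these were the neutrophil list in sham blood (0.855, replicate 5 lowest), the MHC class II list in LPS blood (0.747, replicate 3 highest), the complement list in sham blood (0.883, replicate 2 highest), the natural killer list in mild CLP (0.712, replicate 5 lowest), the heat shock list in saline (0.88, replicate 5 lowest) and the glycolysis list in normal blood (0.755, replicate 5 lowest). In mouse spleen they were Cebpb in CLP (0.558, replicate 5 highest), Lilr4b in CLP (0.643, replicate 1 lowest) and Alb in sham (0.67, replicate 5 highest). In sham blood they were Cxcl13 (1, replicate 2 highest, by 0.578 over the other 3 at the floor), Saa3 (0.905, replicate 2 highest), Ifitm6 (0.923, replicate 5 lowest) and Ccl2 (1, replicate 5 highest, by 0.0808 log2 over the other 3 at the floor). The others were Ccl9 in LPS (0.904, replicate 4 lowest), Cxcl13 in saline (1, replicate 1 highest, by 1.01 over the other 3 at the floor) and Cxcl9 in CLP blood (0.767, replicate 5 highest).

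The effect of CLP differed between spleen and blood in 5 lists, tested as an interaction of tissue and operation with the preset correlation, each with an adjusted p = 0.563 with an estimated correlation. Medians here are over the members tested in both tissues (15, 11, 16, 20 and 25) and so differ from those of each tissue alone. The spleen effect minus the blood effect had a median of −0.532 for the neutrophil list (0.693 in spleen, 1.34 in blood, adjusted p = 0.00375), 0.436 for MHC class II (0.333 and −0.0964, 0.0174), 0.349 for B cells (0.393 and −0.0869, 3.79e-05), 0.148 for cell cycle (0.119 and −0.0423, 0.0195) and 0.26 for the respiratory chain (0.459 and 0.2, 0.00375). This interaction was not repeated under other settings. In spleen alone the B cell call was lost with the RNA quality covariate, matched arrays, equal spread, quantile normalization and the 50th percentile filter, and without any 1 of 7 arrays, and the neutrophil call with that filter and array weights and without 1 array. In blood alone the MHC class II and respiratory chain calls were lost with quantile normalization and other settings, and the cell cycle list passed in neither tissue.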

How the results depend on the processing

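No named gene, and no list that passed in the main fit, was called in the opposite direction under an alternative. The majority direction of the calls turned in mouse spleen, from 58.8% higher to 40.3% with quantile normalization and 44.7% with equal spread, and in infected blood, from 71.3% to 43.5% with quantile normalization. Some lists passed only under alternatives. The acute-phase list was higher in mouse spleen in 3 settings, among them the RNA quality covariate and matched arrays. The respiratory chain list was higher in 10 settings of the CLP minus LPS contrast. The liver list in CLP+ABX against CLP was higher in 7 settings and lower in 1. Against normal blood, the acute-phase and liver lists were higher after sham in fits of these groups only. After saline, such fits gave lower neutrophil and pancreatic lists and a higher macrophage list. The pancreatic list was also lower after saline without normal replicate 1 or 2 or saline replicate 3. Without saline replicate 4 the erythroid list was higher after saline. In LPS against saline, each of these saline lists was called in the opposite direction. Of the results for single named genes 1691 stayed on their side of the threshold and 134 became weaker, of which 28 did so without 1 array, 25 without the replicate block and 19 without the filter on dim probe sets. The 1691 include genes named as not passing, which could not become weaker. All fits without 1 array count as 1 result per gene. The RNA quality covariate, matched arrays, common ceiling and equal spread were chosen after seeing the data. Counts that moved by over 1.5 times follow, and the cause was not tested except where fewer samples or probe sets entered. In mouse spleen, 4226 calls became 2591 with the floor at the 40th percentile, 6555 with array weights, 1260 with the RNA quality covariate and 10 on matched arrays. Without the replicate block, the blood counts were 190 for CLP, 35 for LPS, 367 for mild CLP, 47 for CLP+ABX, 937 for infected blood and 2 for the CLP minus LPS contrast. In fits of the compared groups only they were 67 for LPS, 365 for mild CLP and 72 for CLP+ABX, and this setting gave no separate value for infected blood. Without the filter they were 105 for LPS, 129 for CLP+ABX and 1 for the contrast, with array weights 346, 94 and 104, and with 1 probe set per gene 154 for CLP+ABX. The contrast also gave 8 with quantile normalization, 12 with a 50th percentile filter, 7 with the floor at the 40th percentile and 5 with the RNA quality covariate. Leaving out 1 array gave 0 to 1 in human spleen, 169 to 714 for CLP, 72 to 195 for LPS, 330 to 1267 for mild CLP, 38 to 547 for CLP+ABX and 1 to 118 for the contrast, and, within 1.5 times, 3089 to 4926 in mouse spleen and 1508 to 2040 for infected blood. The classifier placed 30 arrays correctly under each alternative of its size and centring. A fit of mouse spleen with the replicate number as a block called 4832, but the numbers mark no pairing, as same-numbered arrays deviated together with a mean correlation of 0.19 (−0.649 to 0.776) and 2 of 16 correlated best with their own number. Array intensity limits dim genes, since 17.56% to 24.21% of the values on an array lay at the floor.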

Other observations

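The batch contrast of liver markers and the genes of this part were chosen only after the result was seen. Genes of lists that did not pass as a whole also moved in blood. In infected blood the death receptor Fas was higher by 0.50 and the matrix protein gene Fn1 by 1.03. After LPS the survival gene Bcl2l1 was at −0.62 (limma adjusted p = 0.00325) and the coagulation factor gene F5 at −0.36 (0.0169).

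Liver markers in blood differed between batches. Batches 4 and 5 exceeded batches 1 to 3, without CLP+ABX replicate 1, by 4.32 for Fga, 3.23 for Hpx, 3.1 for Fgg, 3 for Rbp4, 2.34 for Apoa1, 2.04 for Alb, 2 for Fgb, 1.97 for Apoa2, 0.884 for Ambp, 0.719 for Apoh, 0.399 for Ahsg and 0.186 for Ttr (log2), and the list means by 2.02 for liver and 0.909 for acute-phase genes. That replicate exceeded the other arrays of batch 1 by 3.05 for the liver list and 2.05 for the acute-phase list. In batches 1 to 3 Fgb stood at the floor (6.49, SD 0), and Fga, Rbp4 and Fgg stood near it (6.55, 6.56 and 6.65). The batch differences of these genes are therefore understated. No explanation was tested.

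The effect of CLP in spleen and in blood differed for 728 of 7514 probe sets tested in both, 279 higher and 449 lower in spleen than in blood. The first principal component held 74% of the variance in mouse spleen, 36% in blood and 30% in human spleen. In mouse spleen the groups overlapped on it, at −6.49 to 31.9 in CLP and −37.4 to 10.9 in sham. Its highest array, CLP replicate 5, had the widest interquartile range (2.444), and its lowest, sham replicate 6, the narrowest (2.017). The 74% is therefore not a measure of the CLP effect alone.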
